A study of Mus musculus with 8 samples.

How the data were processed

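RNA from the cortex of 8 mouse embryos at embryonic day 18.5 was measured on Affymetrix mouse exon arrays, 1 array per embryo, 4 wild type and 4 Ptbp2 knockout. Per the labels' protocols, the animals had a mixed CD1 and C57BL/6 background, RNA was extracted with Trizol, and it was labelled with the Affymetrix whole transcript sense target assay. The series design states that the samples are biological replicates. The deposited values are log2 signals per probe set, which per the submitters' processing notes involved Affymetrix Expression Console, RMA and the mm9 build; software versions and the role of each are not given in the sources used here. RMA combines background correction, quantile normalization and a summary over probes, so differences in total RNA between arrays are removed and low signals are compressed. The array medians of the deposited log2 values lay between 6.82 and 6.93, and no 2 arrays were identical. Arrays give no count depth, and their number limits the precision.

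The table held 625534 probe sets. A platform annotation gave exactly 1 gene symbol to 303629 of them, several to 5892 and none to 316013, and no probe set with several symbols was named. Of 21634 symbols, 17657 were current in the RefSeq gene table of assembly GRCm38.p6 and 3919 were updated through its synonyms. That table was used only for names and for the order of neighbouring genes. Genome positions of probe sets and their exons were not used here, so a usage call names a probe set and not an exon. A probe set was retained if its mean over the 8 arrays was at least the median of the table (6.84), which left 312767. A gene was tested if it had at least 4 retained probe sets, which gave 12960 genes, and its value on an array was the median of those probe sets.

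Levels of genes and of single probe sets were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with no covariate and with Benjamini-Hochberg adjustment at 0.05. Usage was tested on 195604 probe sets with limma diffSplice, which sets a probe set against the others of its gene, and per gene with its Simes p. The splicing index, a probe set minus the median of its gene fitted by eBayes, was an alternative. Ptbp2 was left out of usage counts and list tests. Of 30 gene lists, 29 were tested with camera (preset correlation 0.01; estimated correlation and fry as alternatives) and 27 for enrichment in differential usage with two-sided Fisher's exact tests against all other genes tested, with Benjamini-Hochberg adjustment over lists; sex-linked genes served as a check of the samples. For genes with few or many probe sets, 10000 random draws matched on their number were made. Unless said otherwise, an adjusted p is from limma.

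Design, alternatives, lists and the rule for named genes were fixed before the data were examined. At gene level the rule takes Ptbp2, Ptbp1, Ptbp3 and the 10 largest rises and 10 largest falls past the threshold without overlap between groups. For usage it takes 1 probe set per gene, the 10 most raised and 10 most lowered, and every published target past the threshold. For lists it takes up to 4 members with the smallest p. Map4, Mvk, Add1, Kmt2a and other genes named outside this rule were chosen after their values were seen.

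The fits were tested on simulated arrays made from the real means and spreads for this comparison. Of 100 genes changed by a log2 of 1, 90% were recovered among 12914 tested with equal spread within a gene and 91% among 12927 with each probe set's own spread; for a log2 of 0.5 the shares were 21% and 36%. Of 100 probe sets shifted by 1, diffSplice recovered 52% and 63% and the splicing index 15% and 33%; for a shift of 1.5 the shares were 84% and 87%, and 58% and 60%. False calls outside the changed genes numbered 7 and 9 at gene level, 1 and 293 with diffSplice, and 1 and 6 with the splicing index.

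Alternatives were each array left out, the replicate number as a block, no filter and a filter at the 75th percentile, quantile and cyclic loess normalization of the retained probe sets, eBayes with trend and robust, array weights, the Xist level as a covariate, the mean in place of the median, a minimum of 1 probe set per gene and other thresholds. Fits without wild type 3 and knockout 3 together, calls without overlap only, calls in both usage models and the splicing index with trend and robust were added after the data were seen. Results were also compared over the 35 splits of the 8 arrays into groups of 4.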

Results

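Affymetrix mouse exon arrays were used to measure RNA from the cortex of mouse embryos at embryonic day 18.5. The samples fell into 2 groups, 4 wild type embryos and 4 embryos without a functional Ptbp2 gene, with 1 array per embryo. Ptbp2 encodes the neuronal polypyrimidine tract binding protein, an RNA-binding repressor of alternative exons. An exon array carries many probe sets per gene, so both the level of a gene and the relative signal of single probe sets within it (probe set usage) could be compared. The median log2 signal per array lay between 6.82 and 6.93, and the number of arrays limits the precision of every comparison. On the first 2 principal components of the gene-level values, which held 28.9% and 22.6% of the variance, wild type 3 and knockout 3 lay farthest from the other arrays. Xist was high and the Y-linked gene Eif2s3y low in 2 arrays of each group, so the sexes were balanced.

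The targeted gene was compared as a check of the labels. Ptbp2 fell from 11.20 ± 0.14 (SD, n = 4) in wild type to 5.95 ± 0.34 (SD, n = 4) in knockout cortex, a log2 fold change of -5.25 (SE 0.14). The knockout mean of the gene, a median over its probe sets, lay below the signal filter of 6.84 and was not shown to be above background, so this value is not an exact size of the fall. The limma adjusted p was 1.7e-12, and the two-sided exact permutation p was 0.0286, the smallest that 4 against 4 arrays allow. Of the 18 Ptbp2 probe sets that passed the signal filter, 17 fell, by log2 fold changes between -6.33 and -3.11. Of these 17, 5 kept knockout means above the filter, namely 5255394 (9.18), 4790319 (9.07), 4665591 (8.03), 5291671 (7.40) and 5492107 (6.89). Probe set 4698759 did not fall, at 8.15 ± 0.24 in wild type and 8.35 ± 0.15 in knockout cortex (n = 4 each, log2 fold change 0.19, limma adjusted p = 0.80). Its place relative to the deleted part of the gene was not known here, and a probe set outside that part would check nothing. Of the paralogs, Ptbp1, which is expressed in progenitors and most non-neuronal cells, had a log2 fold change of 0.0028 (SE 0.095, adjusted p = 1.0), with a sign that turned under cyclic loess and array weights (-0.073 to 0.061 over all settings) and without wild type 2, wild type 3 or knockout 4 (-0.040 to 0.056 with 1 array left out). Ptbp3 had a log2 fold change of 0.088 (SE 0.10, adjusted p = 0.95). Neither passed the test.

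**Figure D1:**
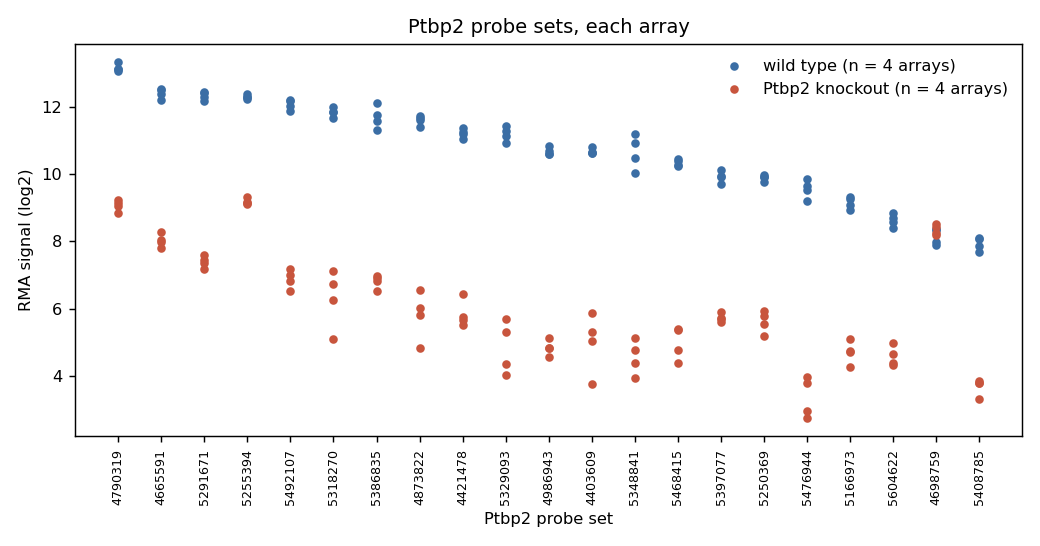
Signal (log2, vertical axis) of each of the 21 probe sets named to Ptbp2 (horizontal axis, ordered by wild type mean) on each array; blue points are the 4 wild type arrays and red points the 4 knockout arrays. The groups are apart for every probe set but 4698759, where the means are 8.15 and 8.35.

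Outside Ptbp2, the largest falls in level were in Cdkl2, a cyclin-dependent kinase-like kinase, and Dzip1, a zinc finger protein of the ciliary base. Cdkl2 fell from 8.36 ± 0.22 to 7.08 ± 0.18 (SD, n = 4 each; log2 fold change -1.29, SE 0.12, limma adjusted p = 1.0e-04). Dzip1 fell from 10.33 ± 0.15 to 9.19 ± 0.21 (log2 fold change -1.14, SE 0.12, adjusted p = 1.8e-04). Snap25, a SNARE protein of synaptic vesicle fusion, fell from 10.90 ± 0.20 to 10.06 ± 0.16 (log2 fold change -0.84, SE 0.11, adjusted p = 0.0048). Spp1, the secreted phosphoprotein osteopontin, rose from 8.25 ± 0.33 to 9.41 ± 0.32 (log2 fold change 1.16, SE 0.16, adjusted p = 0.0061), and Tyw1, an enzyme of wybutosine tRNA modification, rose by 0.97 (SE 0.11, adjusted p = 5.9e-04).

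In all, 15 of 12960 genes passed the threshold, 7 higher and 8 lower with Ptbp2 among them, and in each the 4 knockout values lay on one side of the 4 wild type values, which chance gives in 2.86% of genes and which held for 3.65% of all genes tested. At an unadjusted p under 0.05 there were 841 genes, where 648 would be expected by chance. The other genes that rose were Sfmbt2, a Polycomb group protein (0.93), Osbpl5, an oxysterol-binding protein relative (0.70), Itprid1 (0.65), the orphan receptor Gpr26 (0.62) and the amylase gene Amy1 (0.61), with adjusted p between 0.0061 and 0.034. Amy1 was also among the 100 tested genes nearest to Ptbp2 in gene order. The other genes that fell were Tmem196 (-0.86), the Ras exchange factor Rasgrf1 (-0.65), the vesicle priming protein Unc13c (-0.62) and the receptor tyrosine phosphatase Ptprm (-0.53), with adjusted p between 0.019 and 0.037. Cdkl2, Dzip1, Tyw1, Spp1, Osbpl5 and Snap25 passed whichever single array was left out, and Sfmbt2 lost its call without wild type 2 (adjusted p = 0.066). Each of the other 7 lost its call in 6 to 8 of the 8 fits. The count was 7 without wild type 2, 9 without wild type 4, knockout 1, knockout 2 or knockout 3, and 9 without wild type 3 and knockout 3 together, where Spp1 also lost its call (adjusted p = 0.098). Spp1 (adjusted p = 0.25) and Osbpl5 (0.19) lost their calls with no signal filter, as did those 7 genes, and with a minimum of 1 probe set per gene (0.054 each), as did Sfmbt2 (0.054) and the same 7. The level of Tyw1 was 0.57 with the filter at the 75th percentile (adjusted p = 0.045). The level of Gpr26 was 0.065 with the filter at the 75th percentile (adjusted p = 0.96) and 0.17 with the mean of its probe sets, the level of Itprid1 was 0.39 with the mean and 0.41 with no filter, and Ptprm lost its call in 5 of 11 alternatives.

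**Figure D2:**
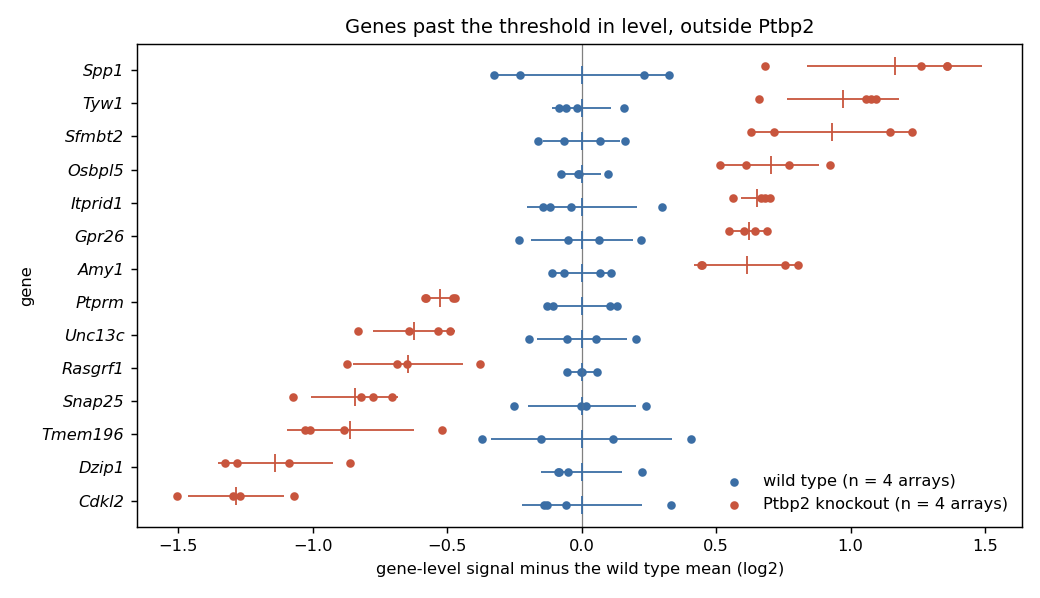
Gene-level signal minus the wild type mean (log2, horizontal axis) for the 14 genes past the threshold outside Ptbp2 (vertical axis). Points are single arrays (blue, 4 wild type; red, 4 knockout), vertical ticks the group means and bars 1 SD; no knockout value overlaps a wild type value of the same gene.

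Gene lists fixed before the data were examined were compared next, to ask whether cell type markers or pathways differed together. Genes typical of striatum, hippocampus and thalamus were lower, with 11 of 17 below wild type. Tac1, the substance P precursor, had a log2 fold change of -0.75 (SE 0.15), Penk, the enkephalin precursor, -0.47, the transcription factor gene Ebf1 -0.45 and Ikzf1 -0.37. Of this list, 7 members passed when adjusted over the list alone and 0 over all genes tested, with limma, while 7 were lower at an unadjusted p under 0.05. The list mean was -0.17, and -0.11 without knockout 3. By array, knockout 4 was at 8.88, above every wild type array (8.76 to 8.87), and knockout 1 to 3 were at 8.69, 8.59 and 8.49. The camera adjusted p was 2.4e-04 with a preset correlation, and adjusted p = 0.54 with an estimated correlation. Choroid plexus and ependymal genes were lower in 12 of 12, with a mean of -0.34 (camera adjusted p = 1.6e-04 with a preset correlation, adjusted p = 0.54 with an estimated correlation). With limma, 0 passed when adjusted over the list alone or over all genes, and 4 were lower at an unadjusted p under 0.05. In knockout 2, Ttr, the transthyretin gene abundant in choroid plexus, was at 9.36 against 13.2 to 13.4 on the other 7 arrays. Without that array the list mean was -0.11 (camera adjusted p = 0.038), and with the filter at the 75th percentile it was -0.56. Presynaptic release genes were lower in 18 of 25 (camera adjusted p = 3.6e-04 with a preset correlation, adjusted p = 0.67 with an estimated correlation), and Snap25 and Unc13c passed both over the list alone and over all genes. Syn1 (-0.27) and Syt1 (-0.24) did not pass. The mean of this list was -0.13, against -0.085 without wild type 1 and -0.073 under array weights, and its median was -0.072. By array, knockout 1 (9.996) lay above wild type 2 (9.962) and wild type 4 (9.951), so the groups overlapped. Knockout 2 to 4 (9.81 to 9.88) lay below every wild type array.

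By limma camera with a preset correlation of 0.01, 8 of 29 lists were shifted. With an estimated correlation none of these calls held, at adjusted p = 0.54 to 0.75 with an estimated correlation and 1 list at an unadjusted p under 0.05. The directional test of fry called 0, with 2 at an unadjusted p under 0.05. Its mixed test, which asks for no shared direction, passed the presynaptic (fry adjusted p = 0.020) and astrocyte (0.036) lists. The 8 were the striatal, choroid plexus and presynaptic lists, together with oligodendrocyte genes (lower in 9 of 9, 0.0060), deep layer neurons (lower in 12 of 17, 0.020) and interneurons (lower in 14 of 18, 0.020). Microglial genes were higher in 9 of 12 (0.0092) and cell cycle genes in 23 of 33 (0.041). Over the list alone, 1 microglial gene passed, the lysosomal gene Cd68 (0.35), and 1 deep layer gene, Ppp1r1b (-0.48), which is also a marker of striatal neurons. No member of the oligodendrocyte, interneuron and cell cycle lists did, and over all genes no member of these 5 lists did. Only 3 gene lists shifted without wild type 1, where the oligodendrocyte (adjusted p = 0.064), microglial (0.084), deep layer (0.095), interneuron (0.084) and cell cycle (0.064) calls ended. The deep layer call also ended without knockout 4 (0.10), and the interneuron call without knockout 3 (0.13). The cell cycle call ended without wild type 2 (0.52), knockout 2 (0.16) or knockout 3 (0.18), with a mean that turned to -0.025 under array weights. The microglial mean was 0.12, against 0.067 without wild type 3 and 0.0039 with the filter at the 75th percentile (adjusted p = 0.93). The oligodendrocyte mean was -0.15 and -0.089 without wild type 1, and the interneuron mean -0.093, against -0.053 without wild type 1 and -0.056 without knockout 3. The deep layer mean was -0.097, against -0.045 without wild type 1 and -0.15 without wild type 3. The cell cycle mean was 0.061, and leaving out any one of the wild type arrays moved it by over 1.5 times, to between 0.011 (wild type 2) and 0.11 (wild type 4). The oligodendrocyte and deep layer calls ended with no filter, the deep layer call with a minimum of 1 probe set, and the presynaptic, oligodendrocyte and interneuron calls under array weights. The cell cycle call ended at the 75th percentile and under quantile and cyclic loess normalization, and without wild type 3 and knockout 3 the presynaptic, microglial and cell cycle calls ended. The other 21 lists, among them radial glia, intermediate progenitors, upper layer neurons, astrocytes, erythroid, meningeal and stress response genes, gave camera adjusted p between 0.063 and 0.88.

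At the level of single probe sets, Tyw1 and Pum2, an RNA-binding repressor of translation, held probe sets that rose. Tyw1 probe set 4495549 rose from 6.87 ± 0.10 to 9.56 ± 0.24 (SD, n = 4 each; log2 fold change 2.69, SE 0.14, limma adjusted p = 4.6e-06). Pum2 probe set 5138709 rose from 8.90 ± 0.24 to 10.77 ± 0.081 (log2 fold change 1.87, adjusted p = 1.4e-04) while the gene as a whole had a log2 fold change of 0.13. In Dnm1, the dynamin of synaptic vesicle endocytosis, probe set 5352752 fell from 10.22 ± 0.23 to 8.24 ± 0.23 and another rose by 1.01. Of 312767 probe sets, 288 passed, 193 higher and 95 lower, and 17 of them were Ptbp2's own. A further 109 were named to 60 other genes, 53 higher and 56 lower, with 14 in Dzip1 and 10 in Cdkl2. The remaining 162 had no single gene name here. The number of probe sets changed was 285 without knockout 2, between 132 (wild type 2) and 191 (wild type 3) without any other single array, and 107 without wild type 3 and knockout 3 together.

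Usage was compared next, to ask which probe sets differed relative to the rest of their gene in the absence of this splicing repressor. Relative to their genes, probe sets of Gpr85, an orphan receptor of the brain (2.03, SE 0.16), Tyw1 (2.02), Pum2 (1.73), Frmd3 (1.61), Rsrc1, an arginine- and serine-rich protein (1.48), and Dbn1, the actin-binding protein drebrin (1.47), were raised. Probe sets of Dnm1 (-1.88, SE 0.14), Pdzd4 (-1.54), Masp1, a protease of the complement lectin pathway (-1.35), and Abi2, an actin regulator of the WAVE complex (-1.24), were lowered. All 10 of these genes passed both in limma diffSplice and in a splicing index model, which gives each probe set its own variance, and outside Tyw1 none of them passed in level. Requiring both models was chosen after the data were seen. It left 17 probe sets in 13 genes, 9 raised and 8 lowered, all without overlap between groups. All 17 splicing index calls were also diffSplice calls, so requiring both gave the splicing index calls and no further support. The remaining genes were Map4, a microtubule-associated protein (0.99), Mvk, mevalonate kinase, and 3010001F23Rik (-1.39, against -0.85 with no signal filter). Frmd3 lay below the signal filter of 6.84 in wild type (mean 6.78), so its deviation is not an exact size. Splicing index adjusted p for these 17 lay between 0.0015 and 0.032. Probe sets of Dnm1, Pum2 (5138709), Tyw1, Gpr85 and Map4, with Masp1 5084572 (-1.05), 6 in all, passed both models whichever array was left out. The other 11, those of Dbn1, Frmd3, Rsrc1, Pdzd4 and Abi2 among them, did so in at most 2 of the 8 fits. Masp1 5370839, the probe set at -1.35, did so in 1 fit and Pum2 5466394 in 0. The count was 6 to 8 without wild type 1, wild type 4 or any knockout array, and 11 without wild type 3. It was 0 without wild type 3 and knockout 3 together, where 3325 passed both at an unadjusted p under 0.05. With all arrays 4258 did so, and no chance expectation was computed for these unadjusted counts. With the replicate number as a block the count was also 0, though the labels state no pairing.

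**Figure D3:**
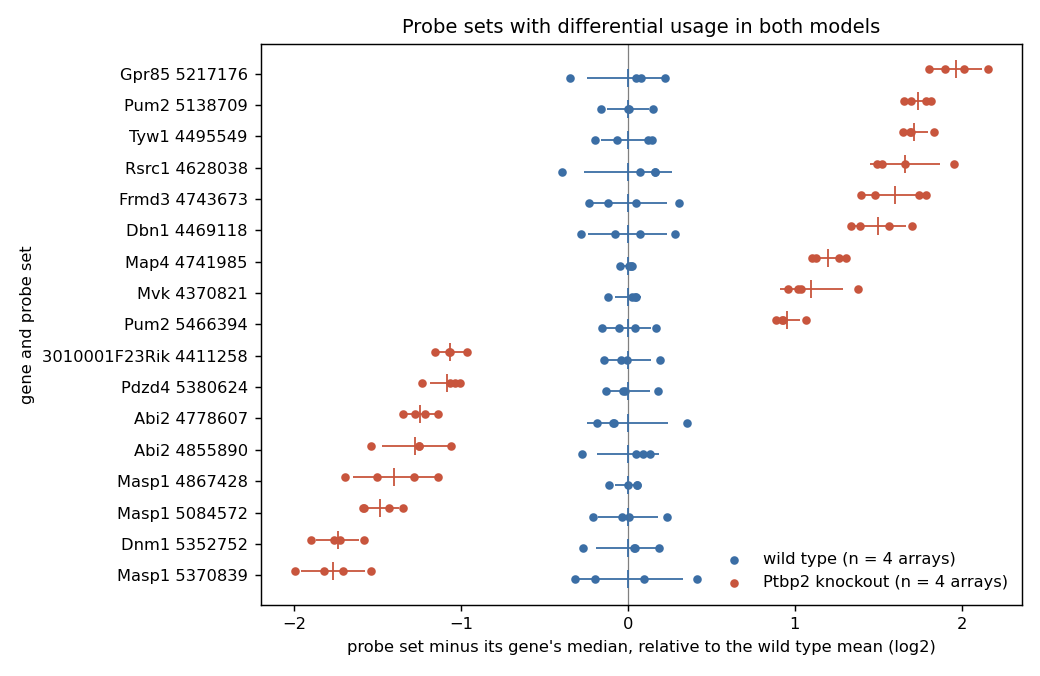
Probe set signal minus the median of its gene, set relative to the wild type mean (log2, horizontal axis), for the 17 probe sets past the threshold in both usage models (vertical axis, gene and probe set). Points are single arrays (blue, 4 wild type; red, 4 knockout), ticks the group means and bars 1 SD; the 9 raised and 8 lowered probe sets show no overlap between groups.

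With diffSplice alone, 414 of 195604 probe sets passed, 172 raised and 242 lowered, and 297 genes passed by the Simes adjusted p. At an unadjusted diffSplice p under 0.05 there were 8930 probe sets, fewer than the 9780 expected by chance. The splicing index gave 10314 at that threshold. Of the 414, 218 showed no overlap between the groups, as did 2.98% of all probe sets tested, where chance gives 2.86%. Since the 414 were selected for a group difference, their share is not a test. Among the largest deviations that the splicing index did not call were Myt1l, a neuronal zinc finger transcription factor (2.40, splicing index adjusted p = 0.092), Dnajc11 (1.42, 0.084), Adamts18 (1.34, 0.23) and Myo15b (-1.30, 0.90). In Cdkl2, probe set 5535451 deviated by 1.40, with a log2 fold change of 0.11 for the probe set and -1.29 for the gene. Probe sets of Htra4 (-1.53), Stab2 (-1.38), Fstl5 (-1.37) and Snx27 (-1.32) passed in diffSplice but overlapped between the groups, and lost their calls in 2 to 5 of the 8 fits with 1 array left out, all of them without wild type 1 and without knockout 3. Without knockout 3, Fstl5 was at -0.56 and Snx27 at -0.52. The mean lay below the signal filter of 6.84 for Myt1l in wild type (6.24) and for Myo15b (6.33), Htra4 (6.47), Fstl5 (6.19) and Snx27 (6.75) in knockout cortex, so these deviations are not exact sizes. In simulated arrays where each probe set kept its own spread, diffSplice gave 293 false calls and the splicing index 6. The simulated spreads carried the error of SDs from few arrays, which can add unequal spread within a gene. The 293 is therefore not an estimate of the false calls among the 414. The number of probe sets with differential usage ranged from 159 without knockout 1 to 856 without knockout 2, and was also moved by over 1.5 times without wild type 1 (213), wild type 4 (227), knockout 3 (164) and knockout 4 (783). Without the same arrays the number of genes ranged from 117 (knockout 3) to 672 (knockout 2).

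Published targets of the polypyrimidine tract binding proteins were then examined, a list drawn from general knowledge that may hold genes described on Ptbp2 knockout brain and is not fully independent. Of 43 tested, 7 had differential usage by diffSplice: Dnm1, Camk2b, a calcium-dependent kinase subunit (-1.11), Sptan1, the spectrin alpha chain (0.84), Tpm3, a tropomyosin (0.76), Ank2, an ankyrin (-0.68), Actn1, an actinin (0.65), and Gabbr1, a GABA receptor subunit (-0.64, overlapping between groups). Of these 7, the splicing index called Dnm1 only. With diffSplice, Tpm3 lost its call without wild type 1, wild type 4 or knockout 1 (adjusted p up to 0.062), Actn1 without wild type 4 or knockout 1 (up to 0.085), Ank2 without wild type 4, knockout 1 or knockout 3 (up to 0.19) and Gabbr1 without knockout 3 (0.91, deviation -0.33). Tpm3 and Actn1 also lost theirs with no signal filter, and Gabbr1 without wild type 3 and knockout 3. The odds ratio was 8.47 (95% interval 3.15 to 19.5, Fisher's exact test, adjusted p = 6.6e-04), and the adjusted p was 0.20 when genes were matched on their number of probe sets. The odds ratio was 12.7 without wild type 1, 5.28 without wild type 2, 3.58 without knockout 2, 18.7 without knockout 3 and 3.97 without knockout 4. Cytoskeleton and actin regulators had 9 of 40, among them Map4, Abi2 and the adducin gene Add1. Their odds ratio was 12.7, with a Fisher's exact adjusted p of 6.1e-06 and a matched adjusted p of 0.011. Dnm1, Sptan1, Tpm3, Actn1 and Ank2 of the published targets were also among these 9, so both enrichments share genes and are not independent. The other 25 lists tested did not pass. The number of lists enriched was 1 without wild type 2, wild type 4 or knockout 2, and 3 without knockout 1. In level, 0 of the 43 targets passed over all genes or adjusted over the list alone with limma, and 5 did at an unadjusted p under 0.05. Dlg4, which encodes PSD-95, had a log2 fold change of 0.25 (SE 0.098, adjusted p = 0.72). Of the 14 genes changed in level, 6 also had differential usage by diffSplice (odds ratio 32.6, 95% interval 9.25 to 108, Fisher's exact p = 3.5e-07), namely Tyw1, Cdkl2, Dzip1, Gpr26, Osbpl5 and Ptprm. That odds ratio was 53.9 without wild type 1, 19.9 without wild type 2, 18.4 without knockout 2 and 13.6 without knockout 4. Both kinds of call are linked, since a probe set that stays constant in a gene whose level changed deviates from that gene. In Cdkl2, probe set 5535451 deviated by 1.40 with a log2 fold change of 0.11 of its own and -1.29 for the gene. The odds ratio therefore does not measure an independent association.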

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

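The test without knockout 2, the requirement of both usage models, the limit to calls without overlap, the comparison of unnamed with named probe sets, the spread of all called probe sets, the splicing index over splits and the standard error set beside the striatal mean were chosen after the results were seen.

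The striatal and choroid plexus lists were lower in the knockout by camera with a preset correlation. With an estimated correlation neither passed (camera adjusted p = 0.54 each). For the choroid plexus part, a knockout 2 sample with little of that tissue is a candidate explanation, since the list mean was -0.112 without it against -0.340 with it. For the striatal part, 16 tested members of a separate marker list had a median log2 fold change of -0.124, with 13 lower. This median was short of the -0.15 set beforehand for less striatal tissue. Its bootstrap interval, -0.222 to -0.0617, resampled markers and not embryos, so it does not measure the spread between animals. The striatal list mean reached at most -0.110 with 1 array left out (without knockout 3; knockout 4 lay above every wild type array), within the standard error (0.0853) of the bound set for 1 or 2 deviating arrays, and the within-group correlation of both lists was 0.327, so neither a few arrays nor a shared dissection difference can be told apart from an effect of the knockout. The striatal mean was as large in 5 of 35 splits (0.165 against at most 0.223 elsewhere). The choroid plexus mean was as large in 4 (0.340 against at most 0.392 elsewhere), so chance cannot be excluded for either.

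DiffSplice called 414 probe sets and the splicing index 17. Unequal spread within a gene, which diffSplice pools, is a candidate explanation of part of the calls, since called probe sets had a median of 1.83 times the within-group SD of the rest of their gene, against 0.854 for all probe sets. The ratio was 2.62 among the 196 calls whose groups overlapped and 1.22 among the 218 others, but overlap selects for a large SD and its absence for a small one, so these parts decide nothing. Chance cannot be excluded for either count, since 8 of 35 splits gave as many calls (414 against at most 1662) and 7 gave as many without overlap (218 against at most 736). The split with 1662 calls set wild type 1, wild type 4, knockout 2 and knockout 4 against the rest, which points to a structure of the samples; it was seen in the diffSplice calls, not in the level or splicing index calls of that split, and was not tested.

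Genes changed outside Ptbp2 might reflect strain variants carried along with the targeted allele, given the mixed background. Of the 14 genes changed in level, 1 (Amy1) was among the 100 tested genes nearest to Ptbp2, which argues against this as the source of 7 or more of them and leaves it open for Amy1. For usage, the share of genes called among these neighbours was 1.31 times that elsewhere (interval 0.272 to 3.73). Only 3 neighbours were called, too few to decide. Ank2, counted above among the published targets, was among them, so its usage call has the same limit. Strain variants elsewhere in the genome, under the probes, were not tested. An effect of the loss of Ptbp2, the difference the design names, stays open.

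The real split gave more genes changed than any other split (15, Ptbp2 among them, against at most 3, 1 of 35). It also gave more probe sets changed (288 against at most 56, 1 of 35). The splicing index gave 17 calls against at most 3 in other splits, a comparison chosen after the results were seen. First of 35 is the best rank that these splits allow, and several results were ranked. The real split thus ranked first in these counts, but that alone does not exclude chance. Chance cannot be excluded for the genes with differential usage (297 against at most 1313, 8 of 35) or the shifted lists (8 against at most 12, 7 of 35). The same holds for the enriched lists (2 against at most 3, 7 of 35). The odds ratio of published targets was as large in 3 of 35 splits (8.47 against at most 25.6). The odds ratios of 25.6 and 10.6 came from splits with 13 and 30 genes with differential usage, against 297 in the real split. Odds ratios from such unlike counts do not compare, so this rank decides nothing, and chance stays open for the enrichment. The overlap of level and usage had an odds ratio of 32.6 against at most 516 (2 of 35). In 32 of the 35 splits no gene changed in level, so the overlap was undefined there and counted as 0. Its count over splits therefore decides nothing. The split with the overlap of 516 followed sex, as read from Xist and Eif2s3y. With the Xist level as a covariate the odds ratio was 24.0.

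In several results 1 array stood apart from the other 3 of its group, by a gap over most of the group's range. Spp1 was at 8.93 in knockout 4, Tyw1 at 9.16 in knockout 2 and Dzip1 at 10.55 in wild type 1. Among probe sets, Pum2 5138709 was at 10.89 in knockout 2, Dnm1 5352752 at 7.90 in knockout 3 and Sptan1 4880606 at 11.55 in knockout 4. The mean of the oligodendrocyte list was 8.58 in wild type 1, that of the choroid plexus list 8.37 in wild type 3, and the array median 6.82 in wild type 2. In all, 9 of 104 groups were of this kind, where chance gives about 5.2.

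A signal also appeared in probe sets with no single gene name, which no comparison by gene uses. Of these, 162 changed, 140 higher and 22 lower, against 53 higher and 56 lower among named probe sets outside Ptbp2. Probe sets of 1 gene are not independent, with 24 of the 56 named falls in Dzip1 and Cdkl2, and among named genes with a single changed probe set 33 rose and 8 fell. Of the 22 unnamed falls, 12 exceeded 3 on the log2 scale, a size reached among named probe sets in Ptbp2 alone; unnamed probe sets of Ptbp2 among them are not excluded, and Ptbp2 was left out on the named side only. The share that changed was 0.149% of unnamed and 0.0533% of named probe sets tested.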

How the results depend on the processing

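The fall of Ptbp2 held in every alternative, with log2 fold changes between -5.35 and -4.73 over all of them. The published target odds ratio (3.42 to 23.6) and the overlap of changed level and changed usage (odds ratio 7.13 to 78.9) kept their direction and an unadjusted p under 0.05 in the alternatives run. The highest target odds ratio, 23.6, came from the splicing index and rested on 1 target, Dnm1, among 14 genes, so it is not a stronger enrichment. Matched on probe set number, the target p was 0.015, and 0.20 adjusted over lists. With 1 array left out, the counts ranged over 7 to 15 genes changed, 132 to 285 probe sets changed, 159 to 856 probe sets and 117 to 672 genes with differential usage, 3 to 12 shifted lists, 1 to 3 enriched lists and 6 to 12 probe sets called by both usage models. Genes changed numbered 7 with no filter, 25 with the filter at the 75th percentile, 24 with quantile normalization, 71 with array weights, 37 with the mean of probe sets and 5 with a minimum of 1 probe set. Probe sets changed numbered 152 with no filter, 461 with trend and robust and 670 with array weights. Probe sets and genes with differential usage numbered 889 and 705 with no filter, 139 and 102 at the 75th percentile, 1920 and 1393 with array weights, 17 and 14 with the splicing index, and 57 and 51 with a deviation of at least 1. Alternatives chosen after seeing the data gave 218 and 183 with calls without overlap only, and 31 and 20 with the splicing index under trend and robust. Without wild type 3 and knockout 3 together there were 9 genes changed, 107 probe sets changed, 247 probe sets and 166 genes with differential usage and 0 probe sets called by both models (3325 at an unadjusted p under 0.05). That last count, also examined after seeing the data, was 7 with no filter, 11 at the 75th percentile, 29 with trend and robust, 34 with array weights and 7 with the Xist covariate. Shifted lists numbered 5 with array weights and 0 with an estimated correlation (1 at an unadjusted p under 0.05) or the directional test of fry (2), and enriched lists 1 each with the splicing index, with a deviation of at least 1 and with matching on probe sets. The cell cycle list reversed to -0.025 under array weights. Leaving out arrays leaves fewer samples to the fit; otherwise the cause was not tested. The replicate block gave 187 probe sets changed and 0 called by both models (5421 at an unadjusted p under 0.05), 22 genes changed and 584 probe sets with differential usage, and ended every call by both models, with no change of call in the named gene levels, the named diffSplice usage or the shifted lists. The labels state no pairing, and same-number correlations of deviations were 0.25, -0.0039, 0.033 and 0.17. Wild type 1 and wild type 4 correlated best with the knockout of the same number. Wild type 2 correlated best with knockout 3 and wild type 3 with knockout 2. Pairing by number was therefore neither shown nor excluded. No chance expectation was computed for the unadjusted counts of both models, so they are not evidence of remaining signal. Signals near the background are compressed, which limits the low-signal genes.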

Other observations

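All values in this part were picked out after the results were seen. Of the genes of excitatory synapses, 2 of 28 passed when adjusted over the list alone, Slc17a7, a vesicular glutamate transporter (log2 fold change -0.49, SE 0.13), and Camk2a, a calcium-dependent kinase of the postsynaptic density (-0.40, SE 0.099), and 0 passed over all genes. Among astrocyte genes, Id3, an inhibitor of helix-loop-helix transcription factors (0.41), and Itih3 (-0.42) passed over the list alone in opposite directions. Map4 had a log2 fold change of -0.54 in level (SE 0.10, limma adjusted p = 0.053, not past the threshold), while 4 of its probe sets fell and probe set 4741985 was raised relative to the gene by 0.99.

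Among named genes outside Ptbp2 with a single changed probe set, 33 had a rise and 8 a fall. Kmt2a, a histone methyltransferase, had 3 probe sets that rose, and Abi2, Efnb3 and Sema4d had 2 each that fell.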
